A study of Mus musculus with 11 samples.

How the data were processed

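RNA was measured in mouse T cells sorted from draining lymph nodes. Of the 11 samples, values of 3 were used: the bulk table of the 2 Tfr libraries and the matrix of the single-cell library. The labels put each sample in its group, and no column of the bulk table was left without a sample or comparison. The column taken for the WT library carries a number that the sample title lacks; it was matched because the labels name no other WT Tfr RNA sample. The 6 Tfh and non-Tfh RNA samples and 2 ATAC samples were not analysed here.

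Per the labels' protocols, bulk libraries were made from Trizol RNA with the NEBNext Ultra RNA kit, and single-cell libraries with version 2 of the 10x Genomics 3′ kit. Per the submitters' processing notes, the tools of the series include TopHat, Cufflinks, Bowtie2, MACS2, bedtools, HOMER, Seurat 2 and Cell Ranger 2.1.0, with the builds mm9 and mm10; the notes give no roles. The matrix was written by Cell Ranger 3.1.0 per the file headers, which differs from the notes. The counter, strand setting and test behind the bulk table are not given in the sources used here. The deposited table gives whole-number counts per gene of each library. Its deposited normalized values are CPM, since each is close to the count scaled by the total of its library, and a count of 0 is shown as 0.5 count. The authors' fold change is the ratio of those values, and the deposited log2 fold change is its logarithm. The deposited p-values come from 1 library per group and do not measure the spread between animals. In addition, 18936 genes had an adjusted p below their p, and the highest adjusted p was 0.357. The adjustment that gave this is not known, and no p-value is used here. At an adjusted p of 0.05 the authors' deposited table holds 15076 genes, 5715 up and 9361 down, and at 0.01 it holds 11081. The deposited single-cell matrix holds UMI counts per gene and barcode.

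Bulk CPM were computed here from the counts and the library totals, 27777625 and 18076300. A floor of 3 counts corresponds to 0.108 CPM in the library labelled KO and 0.166 CPM in the library labelled WT, and a fold against a count of 0 is given as the lower limit of its interval. The table holds 29224 genes, of which 873 had a count of 0 in the library labelled KO and 905 in the library labelled WT. Mitochondrial genes took 1.29% and 0.772% of counts, and the 100 most abundant genes 16.0% and 14.6%, in the libraries labelled KO and WT. Log2 ratios used a pseudocount of 1 CPM. With 1 library per group no test of conditions can be made, so genes were counted by a fixed size, at least 2-fold, among those with at least 5 CPM in at least 1 library. Folds are given with exact conditional binomial 95% intervals, sums of UMIs with exact Poisson intervals and shares of cells with Clopper-Pearson intervals. Reads without molecular identifiers are not independent molecules.

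The 28 gene lists were fixed before the data were examined, as were the size rules, the CPM, gene number and mitochondrial filters, the marker genes and the rule for which genes are named. A list's median over members with at least 1 CPM was placed among 10000 random lists of the same size matched on expression in 20 bins, and called above or below past the outer 2.5% on either side. Lists with fewer than 3 measured members were left out. These percentiles describe the libraries and are no p-values. Named bulk genes were Sostdc1, Foxp3, Cxcr5, Bcl6 and Pdcd1, the 12 highest and 12 lowest log2 ratios, and up to 4 members per list with the largest ratio and at least 5 CPM, leaving out T cell receptor and immunoglobulin segments in the top genes, predicted gene models, small RNAs and pseudogenes. The same rule named 12 genes per direction and 4 per list in single cells, and 10 leading genes per cluster. For 13 symbols on more than 1 line of the table, the line with the highest mean was taken. Gene IDs were matched to a table of names, which held 29173 of them. A RefSeq table of assembly GRCm38.p6 gave overlapping neighbours, chromosome and gene span, and no coordinates from it are printed. It gave a span for 79.9% of all symbols and for 97.8% of the genes with at least 5 CPM, on which the span check was run. No reference genome was used, so base composition was not analysed here.

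Of 15002 barcodes, 835 with under 500 genes and 977 with at least 10% mitochondrial UMIs were left out, leaving 13190 cells. UMIs were scaled to 10000 per cell and log-transformed, and 2000 variable genes, without Sostdc1, receptor and immunoglobulin segments, Xist and Y-linked genes, gave 30 principal components, a graph of 20 nearest neighbours and Leiden clusters at resolution 1. Doublet scores came from simulated doublets, 2 per cell. The threshold search placed its limit at 0.751 and marked 0 cells, so after this was seen the 10% of cells with the highest scores were removed instead, with 146 further cells that had at least 3 UMIs of both B and T cell genes; this took out 1396 cells, or 10.6%, and left 11794. Clusters were named "X-like" from the fixed markers where at least 3 were 2-fold higher than in the other cells, by a scoring rule made after the clusters were seen. Cd3e had a UMI in 79.9% of cells, Cd4 in 55.9% and Cd44 in 31.0%. Cells were thinned to 3000 UMIs to compare shares across depths. Genes compared between Tfh-like cells with and without Sostdc1 had at least 20 UMIs, or 20 expected, in the cells with it, and list members at least 10 UMIs, with 0.5 UMI added to sums. A gene was named at a ratio of at least 2 or at most 0.5 with an interval excluding 1. The result of 1 gene that met this rule is not reported here. A count of such genes had been planned and is not given, because cells of 1 library are not replicates.

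Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. The steps were tested on simulated data. A pair of libraries was simulated from the pooled Tfr proportions with Poisson counting error only, and without spread between animals. Over 9886 genes, the size rule found 100% of genes changed 4-fold, 49% of those changed exactly 2-fold and 0 unchanged genes. Of the intervals, 95.4% held the true ratio. These values cover counting error and not differences between animals. Simulated lists without a shift, drawn from independent values, fell outside their random lists in 5.5% of draws, and 98% of lists shifted by 0.5 were called above. This does not cover lists whose members vary together. Alternatives varied the pseudocount (0.1 and 5), the CPM floor (1, 10 and none), the fold (1.5), the scaling, means for medians, the genes per cell (200 and 1000), the mitochondrial limit (5%), the resolution (0.5 and 2), the variable genes (1000, and without cell cycle genes), the components (15), the doublet removal, the number of Sostdc1 UMIs (2), thinning, marker gates, 3 depth-matched cells per cell with Sostdc1, the UMI floor (50) and the weight of each cell.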

Results

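The series holds 11 mouse samples in 8 groups, all made from T cells of draining lymph nodes, and asks which follicular T cells make Sostdc1 and what its loss does to follicular regulatory T (Tfr) cells. Sostdc1 encodes a secreted antagonist of Wnt and BMP signalling. Values of 3 samples were used. Bulk RNA-seq covered 1 library labelled as Sostdc1-knockout (KO) Tfr cells, with 27777625 counts, and 1 labelled as wild-type (WT) Tfr cells, with 18076300 counts. Tfr cells are Foxp3-expressing regulatory T (Treg) cells that carry the follicular receptors CXCR5 and PD-1, and the labels give a sort on these receptors and on high GITR. A droplet-based single-cell library of CD44-positive CD4 T cells from heterozygous Sostdc1-EGFP reporter mice held 15002 barcodes and 106127466 unique molecular identifiers (UMIs), with 500 to 78924 UMIs per barcode and a median of 5673. The other 8 samples, 6 RNA libraries of follicular helper T (Tfh) and non-Tfh cells and 2 ATAC libraries of Tfr cells, were not analysed here. Each group with values had 1 library, so no difference has a replicate check. Intervals are exact 95% intervals that cover counting error only.

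The targeted gene went against the labels. Sostdc1 (ENSMUSG00000036169) had 458 counts, or 16.5 CPM (counts scaled to a common library total), in the library labelled KO and 4 counts, or 0.221 CPM, in the library labelled WT, a 74.5-fold higher level (28.9 to 275) in the library labelled KO. The labels do not say which part of Sostdc1 is deleted, and reads from a part that remains would still be counted. Such reads would leave some counts in a KO library, but do not by themselves account for a level above that of the library labelled WT. The libraries also differed in genes of the sex chromosomes. Xist, the RNA that silences an X chromosome in female cells, was 571-fold higher (418 to 803) in the library labelled KO, with 34234 against 39 counts. The Y-linked gene Ddx3y had 6 against 3557 counts, Eif2s3y 1 against 1337, Kdm5d 3 against 1206 and Uty 0 against 928, so these were higher in the library labelled WT, Ddx3y by 911-fold (418 to 2484), Eif2s3y by 2055-fold (368 to 81210), Kdm5d by 618-fold (211 to 3000) and Uty by at least 386-fold. Every direction below is stated for the library labelled KO against the library labelled WT and compares these 2 libraries, not the genotypes.

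Several genes for T cell cytokines were far higher in the Tfr library labelled KO. Il21, the Tfh cytokine that drives germinal centre B cells, stood at 82.8 against 4.09 CPM, 20.2-fold higher (16.0 to 25.8), and Il4, which promotes class switching of B cells, was 28.0-fold higher (19.5 to 41.7). Il17f and Il22, cytokines of T helper 17 cells, were 14.6-fold (13.6 to 15.8) and 9.05-fold (8.14 to 10.1) higher. Among the lower genes were Crlf2, the receptor chain for thymic stromal lymphopoietin, at 33.0-fold lower (28.9 to 37.9), and Junb, an AP-1 transcription factor, at 56.3 against 1380 CPM or 24.5-fold lower (23.3 to 25.8). The Treg master regulator Foxp3 stayed abundant in both libraries, at 1164 against 1471 CPM, a ratio of 0.791 (0.778 to 0.804).

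Of 10194 genes with at least 5 CPM in at least 1 library, 265 were at least 2-fold higher and 930 at least 2-fold lower on the scale of log2(CPM + 1), which understates the change of low genes. The median log2 ratio was −0.04, with quartiles of −0.45 and 0.28. Higher genes were 22.2% of those past this size. With scaling by a trimmed mean of log ratios, which moved the median to 0.11, the counts were 415 higher and 688 lower, or 37.6% higher. The authors' deposited table marked 6662 genes as significant, 1682 up and 4980 down, and all 1195 genes past the size rule were among them; a table made from 1 library per group does not measure the spread between animals.

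**Figure D1:**
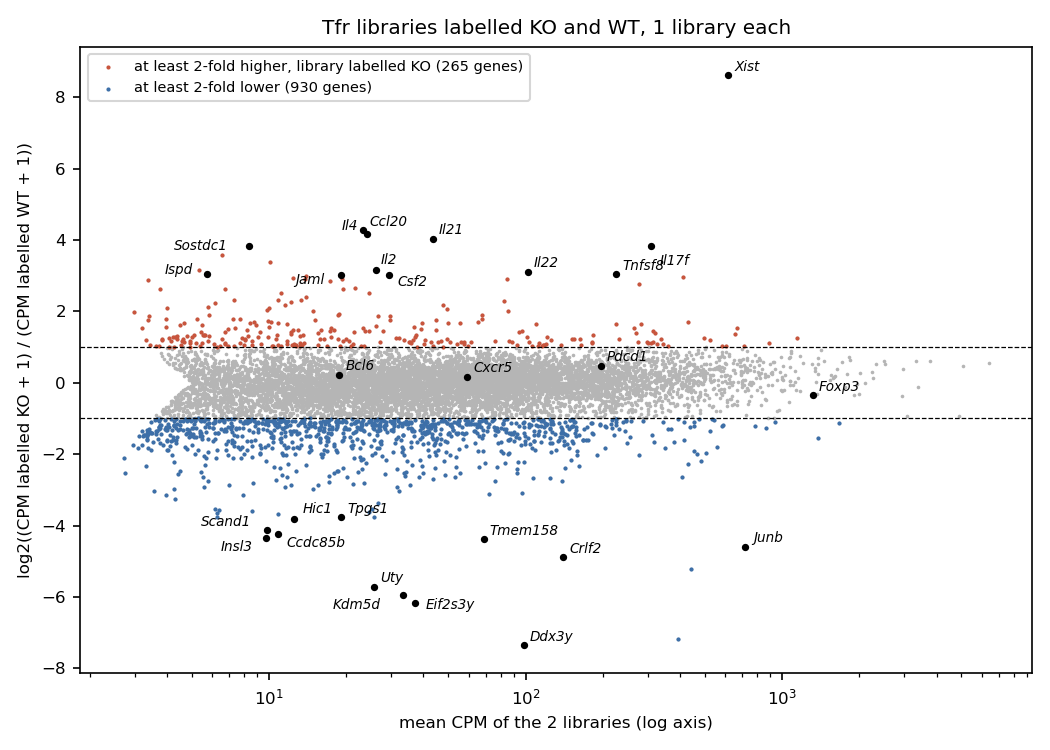
Each point is 1 of 10194 genes, with the mean CPM of the 2 Tfr libraries on a log axis and the log2 ratio of CPM + 1, library labelled KO over library labelled WT, on the other. Dashed lines mark a 2-fold difference, with 265 genes above and 930 below, and named genes are drawn in black.

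The remaining genes among the 12 highest were also mostly immune mediators. Ccl20, the chemokine ligand of CCR6, was 32.8-fold higher (22.1 to 50.8), Il2, the T cell growth factor, 10.7-fold (8.55 to 13.6), and Csf2, which encodes GM-CSF, 9.32-fold (7.63 to 11.5). Tnfsf8, the gene for CD30 ligand, was 8.34-fold higher (7.78 to 8.94) at 404 against 48.4 CPM, and Jaml, a junctional adhesion molecule gene, 10.1-fold higher (7.81 to 13.3). Ispd, which acts in the glycosylation of dystroglycan, was 24.8-fold higher (12.4 to 58.0). Among the lowest 12, Tmem158 was 24.4-fold lower (20.7 to 29.0) and Tpgs1, a tubulin polyglutamylase subunit gene, 20.7-fold lower (15.5 to 28.3). Ccdc85b was 119-fold lower (50.7 to 369), Scand1 108-fold lower (46.1 to 336), Hic1 30.7-fold lower, and Insl3, with 0 against 353 counts, at least 146-fold lower. Those 4 genes overlap other measured genes, Fosl1, Cnbd2, Smg6 and Jak3 in that order, and whether counting used strand is not given in the sources used here. Gene models left out of the naming rule held large differences too, and 2 were picked out after their values were seen, Gm23935 at 4.36 against 782 CPM and Gm26917 at 22.1 against 861 CPM.

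Of the markers of the sorted population, Cxcr5, the follicular homing receptor, stood at 62.8 against 55.7 CPM (ratio 1.13, 1.04 to 1.22), and part of it overlaps Bcl9l. Bcl6, the transcription factor of follicular T cells, stood at 20.3 against 17.2 CPM (1.18, 1.03 to 1.36), and Pdcd1, which encodes PD-1, at 229 against 164 CPM (1.4, 1.34 to 1.46). Tnfrsf18, the gene for GITR, was picked out after its values were seen and stood at 276 against 165 CPM. The Treg core list had a median log2 ratio of 0.24, at percentile 95.4 of its random lists (97.8, a call above, without a filter on low values, and 97.6 without X and Y genes), with 2 of 30 members at least 2-fold higher and 4 lower. Il10, a suppressive cytokine, was 2.17-fold higher and the receptor gene Gpr83 2.85-fold higher, whereas Klrg1, a marker of effector Treg cells, was 2.81-fold lower and Ebi3, a subunit of interleukin 35, 2.58-fold lower. The follicular programme had a median of 0.21, at percentile 96.8 (97.6, a call above, with means), with 3 of 28 members at least 2-fold higher and 1 lower. Its members with the largest differences were the secreted factor Angptl2 (3.12-fold higher), the transcription factor Irf4 (2.60-fold higher), the surface glycoprotein Cd200 (2.24-fold higher) and Id3, an inhibitor of E proteins (4.18-fold lower).

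Of the 28 gene lists, 12 had a median above the central 95% of expression-matched random lists and 3 below it. The Tfh help cytokines and ligands stood highest, with a median log2 ratio of 2.02 and 10 of 12 members at least 2-fold higher. The T helper 1 and cytotoxic list had a median of 1.06, with 10 of 18 members at least 2-fold higher, among them Ifng (6.93-fold), the granzyme gene Gzmk (10.6-fold), the cytotoxic granule gene Nkg7 (4.37-fold) and the chemokine gene Ccl3 (4.13-fold). In the T helper 17 list, with a median of 0.39, 5 of 13 members were at least 2-fold higher, Il17a (7.80-fold) among them. In the T helper 2 list, with a median of 0.42, 4 of 10 were higher, including Il13 (7.86-fold), Il5 (10.1-fold) and the chemokine receptor gene Ccr4 (2.64-fold). Markers of other cell types moved beside these lists. The list for CD8 T, NK and gamma-delta T cells had a median of 0.82, with the NKG2D gene Klrk1 8.05-fold higher and 3 of 6 members at least 2-fold higher, though with members held to at least 5 CPM its percentile was 93.5. The myeloid list had a median of 0.54, with lysozyme Lyz2 2.94-fold and the chemokine receptor gene Xcr1 2.20-fold higher and 3 of 12 members at least 2-fold higher. The B cell list had a median of 0.31, with 3 of 17 members higher and 1 lower, but a percentile of 58.2 when members had at least 5 CPM. Its members went both ways, the MHC class II genes H2-Aa 5.50-fold and H2-Eb1 2.25-fold higher and the immunoglobulin gene Ighm 2.30-fold lower at 473 against 1091 CPM. The plasma cell list, with a median of −0.32, lay within its random lists, but stood above them, at percentile 99.4, when members had at least 5 CPM. Also within were the erythroid and platelet list at −0.72, though at percentile 0.38 without a filter on low values, and the stromal list at −0.07.

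**Figure D2:**
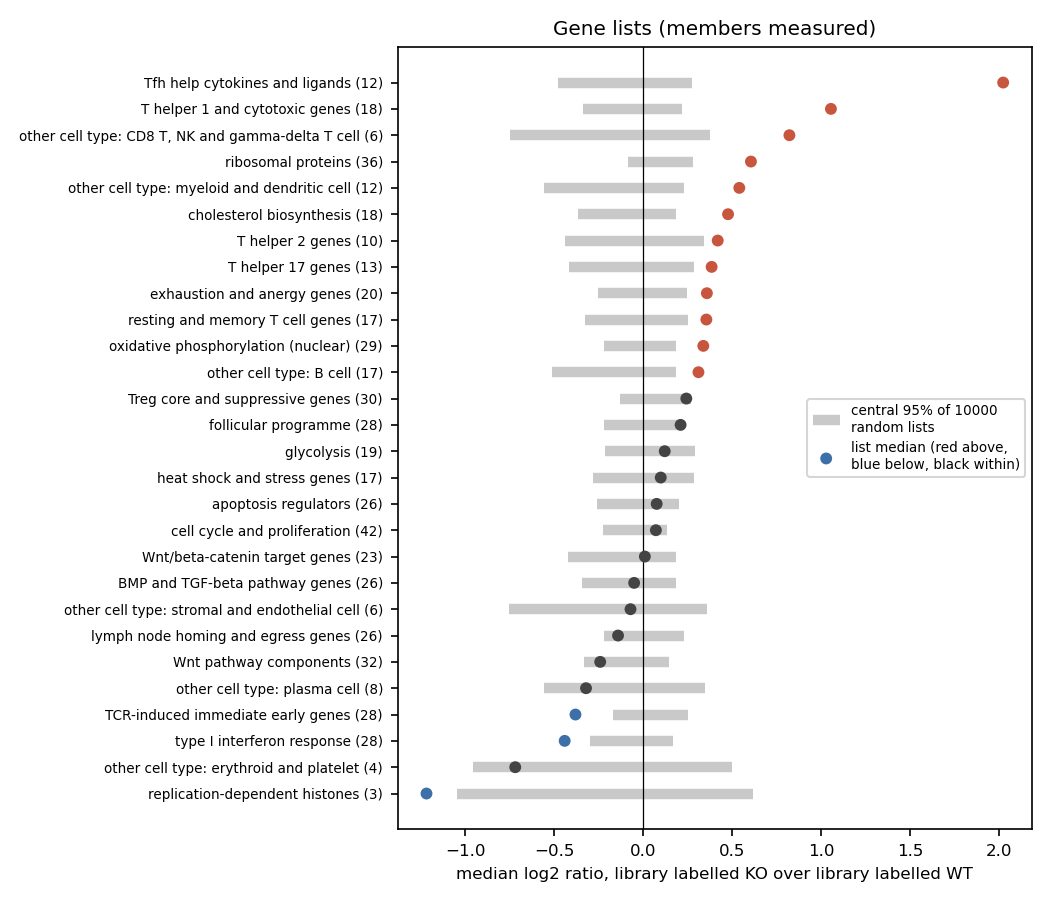
Points give the median log2 ratio of each gene list, library labelled KO over library labelled WT, with the number of measured members in brackets, and grey bars span the central 95% of 10000 expression-matched random lists. The Tfh help cytokines lie farthest above at 2.02 and the histones farthest below at −1.22.

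Immediate early genes, which are induced within minutes of T cell receptor signalling, were lower as a list. Their median log2 ratio was −0.38, at percentile 0.04, with 7 of 28 members at least 2-fold lower and 2 higher. Besides Junb, Ier2 was 5.36-fold and the AP-1 gene Jun 4.01-fold lower, whereas Dusp6, a phosphatase for ERK, was 3.60-fold higher. The type I interferon response list had a median of −0.44, at percentile 0.24, with 5 of 28 members lower and 2 higher; its call ended when means replaced medians, at percentile 3.72. The antiviral tether Bst2 was 3.08-fold and the interferon regulator Irf7 2.21-fold lower, and Ifi204, a DNA sensor, 3.45-fold and Usp18, an ISG15 protease, 2.40-fold higher. Replication-dependent histones had a median of −1.22 over 3 measured members and lost their call with means, at percentile 3.24. Hist1h1c, their member with the most counts, stood at 5.18 against 6.03 CPM.

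Lists of growth and metabolism had few members past 2-fold. Ribosomal protein genes had a median of 0.61, with 3 of 36 members at least 2-fold higher, such as Rps27 (2.62-fold) and Rpl32 (2.28-fold), and 2 lower, Rplp1 (2.33-fold) and Rplp2 (2.20-fold). The cholesterol synthesis list had a median of 0.48 but 0 of 18 members 2-fold higher, with Idi1 1.91-fold and Cyp51 1.87-fold higher and Mvd 2.26-fold lower. Nuclear genes of oxidative phosphorylation had a median of 0.34, and 1 of 29 members, the complex III subunit Uqcrq, was 6.25-fold lower. The exhaustion and anergy list had a median of 0.36, with 2 of 20 members higher, Cd200 and the inhibitory receptor gene Cd160 (2.94-fold), and 1 lower, the anergy factor Egr3 (2.66-fold). The resting and memory list had a median of 0.36, with the quiescence regulator Bach2 4.21-fold and the survival gene Bcl2 3.73-fold higher, and Klf2, which drives lymph node homing genes, 6.70-fold and the egress receptor S1pr1 2.17-fold lower. That list lost its call with means, at percentile 87.6, and without a filter on low values, at 89.7. Within the random lists lay the cell cycle list (median 0.07, with 0 of 42 members past 2-fold, but above with means at percentile 99.1), glycolysis (0.12, with the lactate exporter Slc16a3 3.60-fold lower), heat shock genes (0.10, with the stress genes Ddit4, Hspa1b and Hspa1a 6.52-fold, 6.37-fold and 6.19-fold lower), apoptosis regulators (0.08, with the pro-apoptotic Bbc3 16.5-fold lower and the death ligand Fasl 3.52-fold higher) and homing and egress genes (−0.14, with S1pr4 5.30-fold lower and Cxcr6 3.14-fold higher).

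The pathways on which Sostdc1 acts stayed within their random lists. Wnt target genes had a median log2 ratio of 0.01, at percentile 78.1, with 0 of 23 members at least 2-fold higher and 2 lower. Wnt pathway components had a median of −0.24, at percentile 9.54, with 5 of 32 members lower, among them the Dishevelled genes Dvl3 (2.56-fold), Dvl2 (2.24-fold) and Dvl1 (2.20-fold) and the feedback inhibitor Axin2 (10.1 against 25.2 CPM). Without a filter on low values that list fell below its random lists, at percentile 2.39. BMP and TGF-beta pathway genes had a median of −0.05, at percentile 51.7, with 2 of 26 members higher and 6 lower. The co-receptor gene Tgfbr3 was 3.97-fold higher, and the type I receptor gene Acvrl1 and the ligand gene Bmp7 were 3.23-fold and 2.48-fold lower. Median and mean differed in sign for the Wnt target, heat shock and glycolysis lists.

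The single-cell library asks which CD4 T cells carry Sostdc1 RNA. After filtering, 11794 cells with a median of 5794 UMIs formed 20 clusters. Tfh-like cells made up 9.70% of cells (9.17 to 10.2), in clusters 12 and 7. Cluster 12 was led by Krt83, Padi4, Pdcd1, Cebpa and Ascl2, with Cxcr5 and Il21 also among its leading genes. Cluster 7 was led by H2-Q2, Tubb2a and Tox2. Treg-like cells, led by Gzmb and Itgae or by Lrrc32 and Gpr83, made up 19.4% (18.7 to 20.1). Resting or central memory-like cells held 34.9%, and recently stimulated cells with Egr1, Egr2 and Nr4a1 6.89%. Cycling cells held 6.35%, T helper 1-like cells 5.05%, T helper 17-like cells 4.38%, with the gamma-delta receptor gene Tcrg-C1 among the leading genes of the last, and interferon-response cells 1.99%. B-like, myeloid-like, NK-like and plasma-like cells were present as well. The smaller class shares depend on the settings: interferon-response cells numbered 235, but 1039 with at least 200 genes per cell and 1069 without doublet removal, and no cluster was named as stimulated at resolution 0.5. In several settings part of the resting cells stayed unnamed and Treg-like cells were the largest named class. Among these cells the library held 5 UMIs of Xist, and 3238 cells had a UMI of Ddx3y.

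Sostdc1 RNA was concentrated in Tfh-like cells. Of 1144 Tfh-like cells, 13.9% had a Sostdc1 UMI (11.9 to 16.0), at 91.4 CPM (84.6 to 98.7), and this class held 60.6% of the 1094 Sostdc1 UMIs. Cluster 12 reached 21.8% (17.6 to 26.6) and 155 CPM, above cluster 7 at 10.4% (8.39 to 12.8) and 58.9 CPM. Recently stimulated cells, whose leading genes include Cd200 and Angptl2 of the follicular programme, came next, with 7.38% (5.68 to 9.40), 34.2 CPM and 23.0% of the UMIs. In Treg-like cells the share was 0.394% (0.180 to 0.747), at 0.775 CPM (0.372 to 1.43). B-like cells, which should lack the gene, gave a background of 1.89% (15 of 793 cells) and 3.24 CPM, with a median of 4653 UMIs per cell against 5840 in Tfh-like cells. The shares in Treg-like, T helper 1-like (0.503%) and T helper 17-like cells (0.388%) were below this background. Resting cells had a share of 1.12%, but 45 of their 67 Sostdc1 UMIs lay in cluster 2, at 6.28 CPM (4.58 to 8.41), higher than in B-like cells but with overlapping intervals. The background was itself uneven, with shares of 1.28% and 4.14% in the B-like clusters 9 and 14. Thinned to 3000 UMIs per cell, which left out 53 Tfh-like and 106 B-like cells, the shares were 10.4% in Tfh-like, 4.18% in stimulated, 0.788% in resting and 0.582% in B-like cells, the last 2 with overlapping intervals. The thinned Treg-like share was 0.201%, with an interval that also overlapped that of B-like cells. Cycling cells, with a median of 19502 UMIs, had a share of 2.80%, or 0.938% thinned. In cluster 20, a group of 48 dividing cells with the mitosis genes Cdc20 and Ccnb2, 12.5% had a Sostdc1 UMI, at 15 CPM (7.49 to 26.9), and 2.22% did after thinning.

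**Figure D3:**
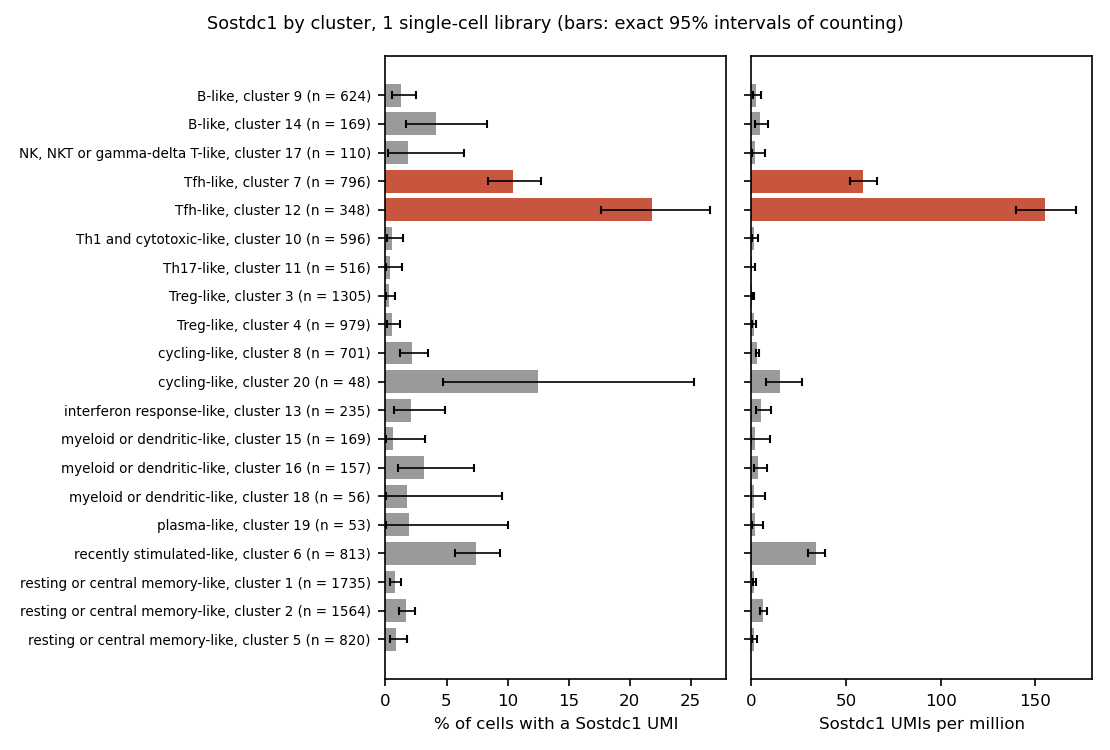
Bars give, for each of 20 clusters of the single-cell library, the percentage of cells with a Sostdc1 UMI and the Sostdc1 level in CPM, with exact 95% intervals of counting. Tfh-like clusters 12 and 7 (red) stand at 21.8% and 10.4%, and the Treg-like clusters below 1%.

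Gates on marker UMIs, which do not depend on the clustering, gave the same order for Tfh and Treg cells. In the Tfh gate (Cxcr5 and Pdcd1 without Foxp3), 16.1% of 765 cells had a Sostdc1 UMI (13.5 to 18.9; 10.6% thinned), at 80.0 CPM. The Treg gate (Foxp3 without Cxcr5 and Pdcd1) gave 0.640% of 1719 cells (0.320 to 1.14), and the non-Tfh gate, without any of the 3 markers, 1.15% of 6719 cells. That last gate also took in 515 B-like and 340 myeloid-like cells. Of the 252 Sostdc1 UMIs of recently stimulated cells, 142 lay in their 120 Tfh gate cells and 24 in their 293 non-Tfh gate cells. For cycling cells, 45 of 60 lay in 83 Tfh gate cells and 1 in 163 non-Tfh gate cells. The Tfr gate (Foxp3, Cxcr5 and Pdcd1 together) gave 7 of 83 cells, or 8.43% (3.46 to 16.6), at 39.6 CPM. Of its 42 Sostdc1 UMIs, 39 lay in 5 of its 20 cells from Tfh-like clusters, and the 35 cells of Treg-like clusters held 1.

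Tfh-like cells with a Sostdc1 UMI were set against the other Tfh-like cells, as a stand-in within 1 library for the reporter sort. The 159 cells with and 985 cells without such a UMI had median depths of 5875 and 5834 UMIs, and the ratio of 5796 compared genes had a median of 1.02. Cells with Sostdc1 had more RNA of the follicular genes Rgs16, a regulator of G protein signalling (ratio 2.77, 2.12 to 3.59), and Ascl2, which drives Cxcr5 expression (2.05, 1.51 to 2.75). They had less of the homing regulator Klf2 (0.440, 0.327 to 0.581), though 0.844 without doublet removal, and of Il7r, the interleukin 7 receptor (0.469, 0.301 to 0.699), though 0.722 in cells with at least 2 Sostdc1 UMIs. Cluster 12 held 47.8% of the cells with and 27.6% of those without Sostdc1, so the pooled ratios also contain the difference between the Tfh-like clusters, and no list below kept its call within both clusters.

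Several of the 12 highest ratios rested on few cells. Spp1, the gene for osteopontin, had a ratio of 109 (45.3 to 345) from 94 UMIs in 4 cells against 5 UMIs in 1 cell. Ifng stood at 10.2 (4.79 to 22.7) in 5 against 12 cells and at 4.76 without the cell with the most UMIs in each set. Stfa3, a stefin gene, stood at 9.46 in 3 against 3 cells, Apoc4 at 5.82 in 6 against 6, and Nrgn, which encodes a calmodulin-binding protein, at 10.9 (5.76 to 21.4) in 9 against 9. The lipoprotein gene Apoe stood at 9.43 (7.82 to 11.4), in 16 against 40 cells, and at 1.35 in cluster 7 alone. Broader differences were those of Slc37a2, a sugar phosphate transporter gene, at 4.07 (2.22 to 7.36) with a UMI in 11.9% against 2.74% of cells, Ispd at 3.22 (1.91 to 5.31) in 14.5% against 4.16%, and the G protein gene Gnaq at 3.03 (1.79 to 5.02) in 12.6% against 4.37%. The transcription factor gene Tshz2 at 3.33, the secreted hormone gene Stc2 at 3.12 and the non-coding Chn1os3 at 3.06 completed these 12. Under other settings Spp1 ranged down to 27.9, Ifng down to 2.53, Nrgn from 2.70 to 29.7, Stfa3 from 4.54 to 63.5 and Apoc4 up to 101, and Chn1os3 stood at 1.24 in cells with at least 2 Sostdc1 UMIs. In cluster 7 alone, the Tfh-like cluster with the lower Sostdc1 share, Tshz2 stood at 0.93 and Stc2 at 0.

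Il18r1, a receptor subunit for interleukin 18, was among the lowest, at a ratio of 0.142 (0.0382 to 0.370) with a UMI in 4 against 121 cells. Gal, the gene for the neuropeptide galanin, had the lowest ratio, 0.0753 (0.0301 to 0.156), but its 541 UMIs in the other cells came from 25 cells, and in cluster 7 alone the ratio was 4.06. Creatine kinase Ckb stood at 0.275, the kinase gene Pdik1l at 0.340, Gtpbp6 at 0.444, Dusp7, a phosphatase for ERK, at 0.462, Pdlim1 at 0.466, Gpr18 at 0.467 and Zfp120 at 0.469. Ssh1, which activates cofilin, stood at 0.451 in Tfh-like clusters and at 1.13 in the Tfh gate, where Ckb stood at 0.624, Pdik1l at 0.701, Pdlim1 at 0.761 and Gpr18 at 0.206.

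**Figure D4:**
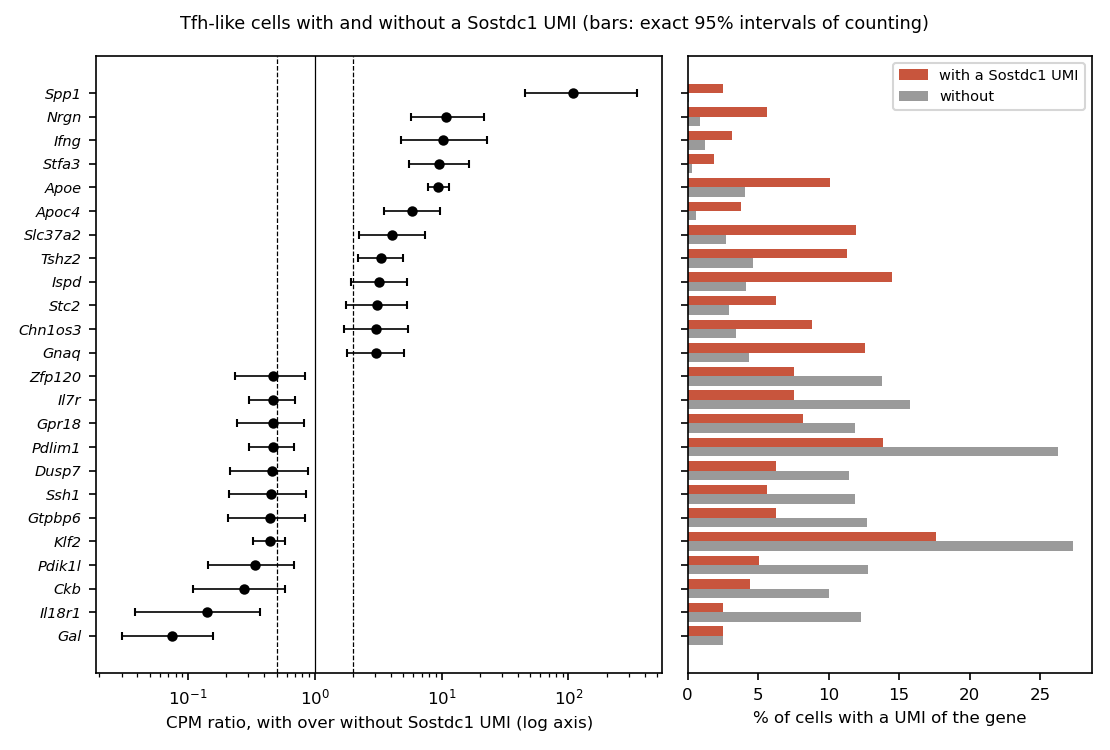
Left, CPM ratio (log axis) of 159 Tfh-like cells with a Sostdc1 UMI over 985 without, for the 12 highest and 12 lowest genes, with exact 95% intervals of counting and dashed lines at 2 and 0.5. Right, the percentage of cells with a UMI of each gene, which is 2.52% against 0.102% for Spp1 and 17.6% against 27.3% for Klf2.

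Of 26 lists with enough members, 8 had a median ratio above and 4 below their random lists. The follicular programme had a median log2 ratio of 0.28, at percentile 100, with Angptl2 at a ratio of 1.70 and Nfatc1 at 1.49 besides Rgs16 and Ascl2. In cluster 12 alone it stood at percentile 30.7. Tfh help cytokines had a median of 0.41, with Tnf at 2.85, Tnfsf8 at 1.58 and Il4 at 1.45, and stood at percentile 44.2 in cluster 7 alone. Immediate early genes had a median of 0.39, with Dusp6 at 2.13 and Nfkbid, a regulator of NF-kappaB, at 2.06, and stood at percentile 67.6 in cluster 7. The exhaustion and anergy list had a median of 0.42, with Cd160 at 2.02 and the inhibitory receptor gene Lag3 at 1.56, and stood at percentile 96.2 in cluster 12. The Treg core list had a median of 0.31 but a mean of −0.04, with the ectonucleotidase gene Nt5e at 1.68 and Ikzf2, which encodes Helios, at 1.49. Glycolysis (0.26), cholesterol synthesis (0.34) and the myeloid list (0.57) were also above, but glycolysis stood at percentile 49.1 in cluster 7, cholesterol synthesis at 0 in the Tfh gate and 80.5 with at least 2 Sostdc1 UMIs, and the myeloid list at 80.6 in the Tfh gate and 83.3 with a floor of 50 UMIs. The myeloid markers thus stood beside the follicular ones, and Apoe leads a myeloid-like cluster of this library too. Below were the homing and egress list (−0.27), which holds Klf2 and the chemokine receptor gene Ccr6 (0.482), the resting and memory list (−0.12), the interferon list (−0.11) and ribosomal proteins (−0.08). Homing genes stood at percentile 6.74 in cluster 7. Wnt targets (−0.05), Wnt components (0.08, with the Wnt receptor gene Ryk at 2.09 and Lef1 at 0.771), BMP and TGF-beta genes (−0.09), heat shock genes (0.06), the cell cycle (0.22), oxidative phosphorylation (0.07), T helper 1 (0.00), T helper 17 (−0.13) and T helper 2 genes (0.26), apoptosis regulators (0.13), histones (−0.07) and the B cell (−0.05), plasma cell (0.12) and CD8, NK and gamma-delta T lists (0.10) lay within. Several of these calls depend on the setting. In the Tfh gate the cell cycle (percentile 0.56), heat shock (1.36), T helper 1 (0.05), T helper 17 (0), B cell (1.23) and CD8, NK and gamma-delta T lists (0.05) stood below. The cell cycle list stood above in cluster 7 (99.5), with a floor of 50 UMIs (98.5) and without top cells (98.8), T helper 17 genes below in cluster 7 (1.66) and with means (1.33), and BMP and TGF-beta genes below without top cells (2.11).

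Receptors on which a Wnt antagonist can act had similar summed levels in both classes of follicular interest. Across all classes the summed level of Fzd1 to Fzd10, Lrp5 and Lrp6 ranged from 1.75 CPM in plasma-like to 30.4 CPM in T helper 1-like cells. It was 24.1 CPM (20.7 to 28.0) in Tfh-like cells, 21.0 CPM (18.6 to 23.7) in Treg-like cells and 18.9 CPM (11.5 to 29.1) in the Tfr gate, and these intervals overlap. Nearly all of it came from Lrp6, at 22.1 CPM in Tfh-like and 18.5 CPM in Treg-like cells, with Fzd5 at 1.93 and 1.71 CPM and Lrp5 at 0 and 3 UMIs. Treg-like cells had more of Wls, which carries Wnt proteins out of the cell, at 75 CPM (70.4 to 79.9) against 11.6 CPM (9.24 to 14.3) in Tfh-like cells, and more of the TGF-beta feedback inhibitor Smad7, at 150 CPM (144 to 157) against 16.6 CPM (13.7 to 19.8). Tfr gate cells lay between, with 38.6 CPM of Wls and 81.1 CPM of Smad7. Tfh-like cells had more of the Wnt effector genes Tcf7 (568 against 78.5 CPM) and Lef1 (149 against 88.0 CPM), of Axin2 (33.7 against 21.0 CPM) and of Id1, a BMP target (6.34 against 0.233 CPM). The BMP receptor genes Bmpr1a (1.24 against 5.97 CPM) and Bmpr2 (3.86 against 8.14 CPM) were higher in Treg-like cells, Tgfbr3 (16.3 against 2.33 CPM) in Tfh-like cells, and Bmp7 was level, at 23.2 CPM (19.8 to 27.0) and 23.3 CPM (20.7 to 26.0). Cells cluster partly by such genes, so the values describe the classes of 1 library.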

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

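The names of the classes in this part rest on a scoring rule made after the clusters were seen. B-like cells also served above as the Sostdc1 background, and the marker gates took in cells of these classes. The sort was for CD44-positive CD4 T cells, and cells of other types were present. B-like cells, with Cd79a and Ms4a1, made up 6.72% of 11794 cells (6.28 to 7.19). Myeloid or dendritic-like cells, with Lyz2, C1qb or Siglech, made up 3.24% (2.93 to 3.57). NK, NKT or gamma-delta T-like cells, with Ncr1 and Klrk1 and also Cd8a, made up 0.933% (0.767 to 1.12). Plasma-like cells, with Jchain and Mzb1 and a median of 22421 UMIs per cell, made up 0.449% (0.337 to 0.587). Droplets with both B and T cell genes, 327 in all, had been removed before these shares were taken.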

How the results depend on the processing

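Settings within the single Tfh-like clusters, random lists matched on span, lists without X and Y genes, the removal of each gene's top cell, the doublet rule and the rule for counting changes of direction were chosen after the data were seen; the others were fixed before. No paired analysis was possible because each compared group has 1 library and no result comes from a test. Among the values that answer a comparison, 87 stayed within their interval or within 1.5 times their count and 40 moved; among the others 647 stayed, 75 moved in size only, 26 lost and 15 gained a call, and 17 changed direction. For the bulk lists, 181 of 194 list calls under alternatives stayed, and the plasma cell list changed direction, from percentile 14.7 to 99.4, with a floor of 5 CPM. Except where construction shows it (a stricter rule, fewer UMIs), the cause was not tested.

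The 265 higher bulk genes became 160 with a pseudocount of 5, 415 with trimmed-mean scaling and 965 at 1.5-fold, and the 930 lower genes 604 with a pseudocount of 5 and 2006 at 1.5-fold. Lists below their random lists, 3 before, numbered 5 without a filter on low values and 1 with means.

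The Tfh-like share of 9.70% became 11.3% with at least 200 genes per cell, 10.3% with at least 1000, 8.90% under 5% mitochondrial UMIs, 15.2% at resolution 0.5, 14.8% with 1000 variable genes, 8.95% with 15 components and 11.5% without doublet removal. The Treg-like share became 23.7% under 5% mitochondrial UMIs. The share of Tfh-like cells with Sostdc1 became 8.04% at 2 or more UMIs, 10.4% thinned and 11.7% at resolution 0.5. For other T cells these values were 0.612%, 0.897% and 1.12%, and for B-like cells 0.126% at 2 or more UMIs and 0.582% thinned. Thinning gave 10.6% in the Tfh gate and 0.776% in the non-Tfh gate.

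Of the 12 genes highest in Tfh-like cells with Sostdc1, 2 were still measured and at least 2-fold higher with a floor of 50 UMIs, and 6 within the cluster of lower Sostdc1 share. Of the 12 lowest, 5 were at least 2-fold lower in the Tfh marker gate, 4 without doublet removal, 4 with the 50 UMI floor, 4 at resolution 0.5 and 5 within the cluster of lower share. Direction changed within that cluster for Tshz2 (ratio 0.927), Stc2 (0) and Gal (4.06), and in the Tfh gate for Ssh1 (1.13). Of these lists, 8 above and 4 below before, the marker gate gave 4 and 10, the cluster of higher share 3 and 2, the cluster of lower share 5 and 1, and means 5 above. The percentile of the Treg core list moved to 26.5 in the marker gate and 40.3 with means, and of the cholesterol list to 0 in the marker gate and 29.2 in the cluster of higher share, where the follicular programme stood at 30.7. In the cluster of lower share, Tfh help cytokines stood at 44.2, resting and memory genes at 59.5 and glycolysis at 49.1. Lists without a call gained 1 on the other side in the marker gate, namely heat shock genes (69.8 to 1.36), the cell cycle (95.8 to 0.56) and CD8, NK and gamma-delta T genes (60.4 to 0.05), and with the 50 UMI floor B cell genes (26.9 to 98.3). On the same side 9 calls were gained, among them in the marker gate T helper 1 (0.05), T helper 17 (0) and B cell genes (1.23). The receptor sum of Treg-like cells, 21.0 CPM, was 17.1 CPM in the Treg gate. Depth limits these cell comparisons, since 159 cells carried a Sostdc1 UMI.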

Other observations

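The test of exchanged labels, the set without cytokines, ligands and Sostdc1, the split by gene span and the genes compared across data types below were chosen after the results were seen; the other tests were written before their own values but after related values had been seen.

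Some genes named in the bulk comparison also differed between Tfh-like cells with and without Sostdc1, and their overlap was not tested. Ispd was 24.8-fold higher in the Tfr library labelled KO and stood at a ratio of 3.22 in the cells with Sostdc1. Cd160 (2.94-fold and 2.02) and Dusp6 (3.60-fold and 2.13) were higher in both, Angptl2 (3.12-fold and 1.70) and Tnfsf8 (8.34-fold and 1.58) had cell ratios short of the size rule of 2, and Klf2 was lower in both (6.70-fold and 0.440, or 0.844 without doublet removal). Others went apart, such as Rps27 (2.62-fold higher and 0.908) and Ighm (2.30-fold lower and 1.23). The immediate early list stood below in bulk (median −0.38) and above in the cells (0.39), and ribosomal proteins (0.61 and −0.08) and resting and memory genes (0.36 and −0.12) the other way round. Ascl2, higher in the cells with Sostdc1, had 3 and 2 bulk counts in the libraries labelled KO and WT, below the floor for list members. A UMI of the proliferation genes Mki67, Top2a, Birc5 or Cdk1 was found in 34.0% of the Tfh-like cells with Sostdc1 (54 of 159) and 25.9% of those without (255 of 985). These shares pool both Tfh-like clusters, and no interval was taken for them.

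Effector cytokine genes and Sostdc1 were higher in the library labelled KO. Foxp3-negative T cells, which the gate on high GITR is meant to leave out, were examined as 1 contributor. The set was 52 genes at least 8-fold higher in Tfh-like, T helper 1-like, T helper 17-like and stimulated cells than in Treg-like cells. Its median log2 ratio was 0.86, above its random lists, with 23 genes at least 2-fold higher and 1 lower. That direction is what such cells would give. The set holds Sostdc1 and cytokines of the pattern itself, and without cytokines, ligands and Sostdc1 41 genes had a median of 0.61. The members with the highest single-cell levels went apart, the chemokine gene Ccl5 at 26.5 against 8.52 CPM and Tox2 at 8.03 against 12.8 CPM. Those highest in bulk, such as Il17a and Il17f, were higher. At 728 and 579 CPM in the library labelled KO, these 2 exceeded the pooled effector cells (58.8 and 38.0 CPM), while Ccl5 lay far below them (420 CPM). Levels of the 2 data types are not on 1 scale, however. Il2ra, a Treg-specific gene, stood at 4002 and 2637 CPM in the bulk libraries labelled KO and WT against 260 CPM in Treg-like cells. These sizes therefore cannot decide whether 1 share of the pooled cells would give both, and mixtures were not tested. Dilution of Treg transcripts stays open, since 35 Treg-specific genes had a median of −0.68, with 13 at least 2-fold lower and 0 higher, but of 12 abundant ones 8 were lower and 3, Il2ra, Lrrc32 and Gzmb, higher beyond counting error; this was first read as in favour, and the reading was changed after these 3 were seen. The 74.5-fold Sostdc1 difference is what exchanged labels or columns would give, but cannot be told apart from other sources of Sostdc1 RNA with 1 library per group. Genotype, sex and the activation of the sorted cells are confounded in these libraries and were not tested.

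More genes were lower than higher in the library labelled KO, immediate early genes among them. Gene span alone could not account for the immediate early list, whose median stayed at percentile 0.44 among random lists matched on expression and span. Across genes, which are not independent, the Spearman correlation of log2 ratio with span was 0.058, inside the bound set beforehand as arguing against a length bias. That bound was judged wrong once genes grouped by span were seen: 15.7% of the group with the shortest spans (median 4.40 kb) but 5.17% of the group with the longest were at least 2-fold lower, and 4.67% and 2.91% higher. A length or base composition bias therefore stays open, and a biological difference was not tested apart from it.

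The libraries differ in sex-linked genes, and the X and Y chromosomes held 2.76% of 1158 genes past 2-fold with a known chromosome, 28 on X and 4 on Y, against 3.09% of all filtered genes. By number, genes of the sex chromosomes were thus a small part of the differences. X and Y genes are too few among the filtered genes to reach the share set beforehand as in favour. The test could therefore not have come out that way, and no more is drawn from it. Effects of sex on autosomal genes were not tested, since sex and label cannot be separated here.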
